A study of Arabidopsis thaliana with 6 samples.

How the data were processed

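3'READS+ libraries of RNA from whole Col-0 seedlings, grown for 1 to 2 weeks and then moved to darkness for 48 h, were compared between seedlings given light for 6 h (Light, 3 libraries) and seedlings kept in darkness for the same 6 h (Dark, 3 libraries), per the labels. The deposited table holds the raw read count of each library at each poly(A) site cluster, given by chromosome, strand and position. Bowtie2 and the TAIR10 build are named in the submitters' processing notes. Their roles and versions, the clustering rule, the read filter and the position convention are not given in the sources used here. All values were whole numbers, and all 6 count columns were mapped to samples by title. Library totals were 13.39, 13.20 and 13.51 M reads in Light and 13.36, 14.51 and 14.53 M reads in Dark. Of the 217870 clusters, 58928 had a single read over all libraries, and neighbouring clusters lay a median of 49 nt apart. No 2 replicates were identical, and the chi-square per degree of freedom of replicate pairs across genes lay between 6.48 and 28.7, highest between Dark replicates 1 and 2, so replicates differed by more than sampling noise.

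Clusters were assigned to the 27444 nuclear protein-coding genes of a RefSeq gene table on the TAIR10.1 assembly, which gave names and neighbours; symbols were listed for 44.8% of genes. Its gene ends and the file's positions were compared over 15 stretches of the chromosomes, where 44.4 to 51.1% of the sites within 600 nt of a gene end lay within 100 nt of it. Mitochondrial coordinates of the file differ from those of the reference, so no organelle gene is named. The table gives no strand, exon or untranslated region. A gene's strand was therefore inferred from the reads around its 2 ends, in a window of 100 nt outside and the larger of 300 nt or 50% of the gene inside, with at least 20 reads and 90% of them on 1 strand. This resolved 18430 genes; 8328 had too few reads and 686 were ambiguous. Clusters on that strand, inside the gene or up to 200 nt beyond it, were assigned to it. Clusters shared by 2 or more genes (2359), antisense to a gene (13421), within 50 nt of a tRNA, snoRNA, snRNA or rRNA gene (1275, with 0.164% of reads), on no protein-coding gene with a resolved strand (34341), mitochondrial (2097) or plastid (262) were left out of the gene tests. The 164115 assigned clusters fell into 18220 genes.

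In place of an annotated 3' UTR, a terminal region was used. Its reference site is the most distal cluster with at least 10% of the gene's reads, and it reaches 400 nt upstream of that site; 124280 clusters were terminal and 39835 upstream. The region stands in for the 3' UTR and is not one, so a site called upstream may lie in a long 3' UTR and a terminal one in coding sequence. The strand window, the reference site and the exclusion at small RNA genes were set after first passes over the results had been looked at, the last after named upstream results had been seen.

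Gene-level tests used edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr (minimum count 10, minimum total 15) and the quasi-likelihood F-test, Light minus Dark, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.126. Site usage was tested with edgeR's diffSpliceDGE and Simes' method on clusters that passed the filter and held at least 5% of their gene's reads; 5642 of the genes had 2 such clusters. Terminal pairs were the 2 most used terminal clusters of a gene under the same minimum, tested as distal over proximal. Upstream shifts compared the summed upstream with the summed terminal reads. The direction of terminal shifts was tested with an exact binomial test, the mean distal share per library with an exact permutation test over 20 arrangements, whose smallest p is 0.1, and the overlap of calls with Fisher's exact test. Errors are SDs over 3 libraries. CPM values use TMM factors. Genes with 1 to 3 reads in a group are given as ratios with a 95% counting interval, and genes with 0 reads against a floor of 3 counts over the group.

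Gene lists (23, of which 22 had at least 4 tested members) were tested with camera of limma 3.58.1 on voom values, with the preset correlation of 0.01, with an estimated correlation and with fry. One listed gene was dropped because its symbol belongs to another locus, and 27 were kept by locus although the reference does not list the symbol first given to them; 9 of these have another symbol there and 18 have none. Lists were also tested for changed site usage with Fisher's exact test, with adjustment over the 20 lists that had enough genes, and again within 5 bins of mean expression with an exact conditional Mantel-Haenszel test; these list usage tests were added after seeing the data.

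All other tests of the report, their alternatives except those named below, the lists and the rule for named genes were fixed before the data were examined. The rule named, of genes called with a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries, the 6 with the largest rise and the 6 with the largest fall. It named for each list the 2 members with the smallest adjusted p, or 1 where the list did not pass, and the called member against the list's direction with the smallest adjusted p. Of called terminal pairs without overlap and with a mean of at least 20 reads at each site, it named the 6 with the largest shift each way, and for upstream shifts 4 each way. Of the 3' end processing and splicing lists it named at most 10 genes called in a site test. Other terminal region lengths (250 and 600 nt), the annotated gene end, pairs at least 100 nt apart, library totals as scaling, small RNA clusters kept and genes not called at the gene level were added after seeing the data. Alternatives also used DESeq2 1.42.0, limma, Fisher's exact test on summed reads, RLE factors, other usage minimums (10% or none), no low-count filter, the outermost terminal sites, a replicate block and each replicate left out in turn. Ratios in limma used a pseudocount of 0.5.

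The fits were tested on simulated data drawn from the real means and library sizes, 5 times with 200 changed genes each. Of genes changed 1.5-fold, 2-fold and 4-fold, the gene-level test recovered 37.0%, 78.5% and 97.9% over 16537 genes. Of simulated calls 6.33% were false, above the nominal 5%. In the data 72.9% of genes were called, far more than the 200 changed per draw, so this share may not carry over. The site usage test recovered 2.09%, 25.7% and 77.3% over 11074 genes with 1.14% false calls, terminal pairs 9.85%, 40.3% and 91.2% over 10976 genes with 6.39% false, and upstream shifts 20.0%, 60.0% and 97.0% over 490 genes with 3.76% false. A list shifted by 0.5 on the log2 scale was recovered in 5 of 5 draws, over 16530 genes. Genes were drawn independently, whereas the estimated correlation within the cytosolic ribosomal protein list was 0.493. The draws therefore cannot show how the list test behaves with correlated genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.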

Results

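Poly(A) site use was measured by 3'READS+, which sequences the 3' ends of polyadenylated RNAs, in whole seedlings of Arabidopsis thaliana, ecotype Col-0. After 48 h without light, plants either received light (Light, 3 libraries) or remained in darkness (Dark, 3 libraries) for 6 h more. The question set by this design is how renewed light changes RNA levels and the choice of poly(A) site. The deposited counts covered 217870 poly(A) site clusters, that is, groups of neighbouring cleavage positions. The totals were 13.39, 13.20 and 13.51 M reads in Light and 13.36, 14.51 and 14.53 M reads in Dark. Of all reads, 97.1% were assigned to protein-coding genes. The number of clusters with reads was 125830 ± 1627 in Light and 107368 ± 2949 in Dark (SD, n = 3 each). The 10 most abundant genes held 6.59% ± 0.16 of assigned reads in Light and 10.8% ± 1.14 in Dark. Across genes, which are not independent replicates, expression correlated at 0.987 or higher between Light libraries, at 0.978 or higher between Dark libraries and at 0.822 or lower between the groups. The labels do not say whether replicates came from separate plantings, so p-values measure only the spread between these samples, which may be technical.

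Light and darkness moved genes in both directions and by large factors. Among called genes with a mean of at least 10 CPM (read counts scaled to a common library size) in the higher group and no overlap between the groups' libraries, those with the largest rises were BBX16, ELIP1, CYP79F1, IPMI2, AK3 and PAP1, each nearly absent from Dark. ELIP1 (AT3G22840), an early light-induced protein of the thylakoid, had 1302 reads in Light and 2 in Dark, a ratio of 498 with a counting interval of 138 to 4118. BBX16 (AT1G73870), a B-box protein, had 854 reads against 1, a ratio of 654 (117 to 25843), and PAP1 (AT1G56650), a MYB regulator of anthocyanin synthesis, had 545 against 1, a ratio of 417 (74.5 to 16503). CYP79F1 (AT1G16410) and IPMI2 (AT2G43100), both enzymes of the aliphatic glucosinolate pathway, had 633 against 1 and 1482 against 3 reads, ratios of 484 (86.6 to 19163) and 378 (129 to 1835). AK3 (AT3G02020), an aspartate kinase, had 578 reads against 1, a ratio of 442 (79.1 to 17500.3). The largest adjusted p among these 6 genes was 5.15e-09 by edgeR's quasi-likelihood test. CYP79F1 has a near-identical neighbour, CYP79F2, with which it could share reads.

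The largest falls in light under the same limits were those of CCD7, AT1G19530, MLO3, DIR5, CYS2 and XTH15. CCD7 (AT2G44990), a carotenoid cleavage dioxygenase of strigolactone synthesis, had 613 reads in Dark and 1 in Light, a ratio of 801 with a counting interval of 143 to 31691. AT1G19530 fell from 9330 ± 532 CPM in Dark to 54.1 ± 9.78 in Light (SD, n = 3 each), a 172-fold change. XTH15 (AT4G14130), a xyloglucan endotransglucosylase/hydrolase of the cell wall, fell 93.6-fold, from 532 ± 58.9 to 5.68 ± 1.75 CPM. MLO3 (AT3G45290) fell from 40.2 ± 4.78 to 0.373 ± 0.172 CPM, and CYS2 (AT2G31980), a cystatin, from 25.8 ± 1.26 to 0.263 ± 0.132 CPM. DIR5 (AT1G64160), a dirigent protein, fell from 17.61 ± 2.22 to 0.173 ± 0.199 CPM. These 3 genes changed 105-fold, 94.9-fold and 95.7-fold, and the largest adjusted p of the 6 falling genes was 3.8e-09.

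Of 16773 genes tested, 12232 (72.9%) passed an adjusted p of 0.05, 6267 higher and 5965 lower in Light. Among them, 7615 changed at least 2-fold, 4106 upward and 3509 downward. Scaling by library totals alone, without normalization factors, shifted the median of all genes by 0.45 on the log2 scale and gave 8625 genes higher and 4012 lower, so that 68.3% of calls were higher in Light against 51.2% in the main test. All fold changes given here are relative to the normalization factors of the main test. The interval and floor of any read count cover counting error only.

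Of 21 light-harvesting complex genes, whose products bind the chlorophyll of both photosystems, 14 were higher in Light, 3 were lower and 4 did not pass. CAB2 (AT1G29920) stood at 1657 ± 129 CPM in Light and 18.24 ± 2.02 in Dark, a 90.8-fold change, while LHCB3 (AT5G54270) rose 12.9-fold and LHB1B1 (AT2G34430) fell 2.44-fold. The CAB genes for LHCB1 proteins are near-identical copies, and how their reads were shared among them is uncertain. Of 25 photosystem and electron transport subunits, 16 were higher, 2 lower and 7 not past the test. NPQ4 (AT1G44575), the PsbS protein of energy dissipation, rose 75.8-fold from 5.96 ± 0.475 to 453 ± 21 CPM, PSAK (AT1G30380) rose 11.1-fold, and PSAE-2 (AT2G20260) fell 1.76-fold. The list shifts passed camera at adjusted p = 7.04e-04 and p = 3.47e-05, and neither held with an estimated correlation, at adjusted p = 0.213 and p = 0.192.

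Of 17 Calvin cycle genes, which fix carbon, 14 were higher in Light, 2 were lower and 1 did not pass. FBA1 (AT2G21330), a plastid aldolase, rose 12-fold and GAPB (AT1G42970) 7.79-fold, but GAPA (AT3G26650), which encodes the other subunit of the same dehydrogenase, fell 2.64-fold from 1701 ± 124 to 644 ± 37.6 CPM. The RBCS genes of this list share long stretches of sequence, so their values are uncertain. The adjusted p was 3.47e-05 by camera and 0.235 with an estimated correlation. Of 10 photorespiration genes, 6 were higher, 2 lower and 2 not past the test, and the list did not pass (adjusted p = 0.122). GLDP1 (AT4G33010), a glycine decarboxylase subunit, rose 17.8-fold, whereas AT1G80380 fell 11.8-fold.

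Of 27 tetrapyrrole synthesis genes, 19 were higher in Light, 5 lower and 3 not past the test (camera adjusted p = 0.00369, or p = 0.213 with an estimated correlation). POR C (AT1G03630), a light-dependent protochlorophyllide reductase, rose 34.1-fold, and G4 (AT3G51820), chlorophyll synthase, rose 14.1-fold from 4.44 ± 0.505 to 62.4 ± 4.14 CPM. TED4 (AT2G26670), heme oxygenase, fell 2.68-fold. Of 17 genes of photoprotection and the HY5 pathway, 12 were higher, 2 lower and 3 not past the test (adjusted p = 0.0195, or p = 0.438 with an estimated correlation). OHP (AT5G02120), a one-helix protein, rose 4.1-fold beside ELIP1, and RUP1 (AT5G52250), a repressor of the UVR8 photoreceptor, fell 7.22-fold. Of 19 genes for plastid ribosomal proteins and sigma factors, 12 were higher, 2 lower and 5 not past the test (adjusted p = 0.015, or p = 0.456 with an estimated correlation), among them the sigma factors SIGA (AT1G64860), 6.19-fold higher, and SIGF (AT2G36990), 2.64-fold higher. RPS9 (AT1G74970) was 2.19-fold lower.

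Of 15 flavonoid synthesis genes tested, 14 were higher in Light and 1, C4H (AT2G30490), was 1.61-fold lower. TT4 (AT5G13930), chalcone synthase, rose 290-fold from 0.635 ± 0.317 to 184.8 ± 47.7 CPM, and TT5 (AT3G55120), chalcone isomerase, rose 4.78-fold. The list's adjusted p was 3.83e-05, or p = 0.213 with an estimated correlation. In nitrate and sulfate assimilation 9 of 10 genes were higher and 1 did not pass (adjusted p = 6.36e-05, or p = 0.192 with an estimated correlation), among them GLU1 (AT5G04140), a ferredoxin-dependent glutamate synthase, at 20.7-fold, and NIR1 (AT2G15620), nitrite reductase, at 8.85-fold. Of 23 cytosolic ribosomal protein genes, 19 were higher and 4 did not pass (adjusted p = 1.82e-05, or p = 0.346 with an estimated correlation), with AT1G70600 at 4.41-fold and RPL18 (AT3G05590) at 3.95-fold. Among 9 cell division genes, 8 were higher and 1 did not pass (adjusted p = 0.00846, or p = 0.346 with an estimated correlation). MCM5 (AT2G07690), a replication helicase subunit, rose 11.6-fold and the D-type cyclin CYCD3;3 (AT3G50070) 5.46-fold.

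Of the 22 lists tested, the list chosen for the response to darkness and starvation had the lowest median. Of 27 tested, 26 were lower in Light and 1 was higher. SEN1 (AT4G35770) fell 31.8-fold from 15261 ± 441 to 479 ± 9.64 CPM, and DIN4 (AT3G13450), a subunit of the branched-chain ketoacid dehydrogenase, fell 20.5-fold from 759 ± 2.3 to 37.0 ± 2.04 CPM. The exception was GBF6 (AT4G34590), a sugar-responsive bZIP factor, which rose 26.9-fold. Of 14 autophagy genes, 13 were lower in Light and 1 did not pass, and ATG8F (AT4G16520) and ATG8E (AT2G45170), ubiquitin-like proteins of the autophagosome, fell 12.3-fold and 9.29-fold. The adjusted p of these lists was 5.18e-13 and 1.82e-05 by camera, and p = 0.192 for both with an estimated correlation.

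Circadian clock genes fell in 21 of 27 cases, rose in 5 and did not pass in 1 (adjusted p = 5.92e-04, or p = 0.236 with an estimated correlation). COR27 (AT5G42900) fell 10.4-fold, AT5G06980 fell 3.92-fold, and ELF4 (AT2G40080), a subunit of the evening complex, rose 9-fold from 8.1 ± 2.4 to 73.0 ± 10.1 CPM. Of 23 photoreceptor and PIF pathway genes, 14 were lower, 5 higher and 4 not past the test (adjusted p = 0.0228, or p = 0.296 with an estimated correlation). HFR1 (AT1G02340), an atypical bHLH factor of light signalling, fell 20.3-fold and PHOT2 (AT5G58140), a blue light receptor, rose 7.18-fold. Of 26 SR proteins and splicing regulators, 17 were lower, 5 higher and 4 not past the test (adjusted p = 0.00373, or p = 0.346 with an estimated correlation). RS40 (AT4G25500) fell 5.69-fold, SR34 (AT1G02840) fell 5.61-fold from 495 ± 55.5 to 88.2 ± 7.77 CPM, and RSZ22a (AT2G24590) rose 4.51-fold.

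Of 29 3' end processing factors, 8 were higher, 8 lower and 13 not past the test (adjusted p = 0.838), including FCA (AT4G16280), an RNA-binding regulator of flowering, 6.31-fold lower, and CPSF100 (AT5G23880), 2.53-fold higher. The auxin response and cell expansion list had 9 higher, 9 lower and 3 not past the test of 21 (adjusted p = 0.942), among them XTH7 (AT4G37800), 45.7-fold higher, opposite to XTH15. Of 14 heat shock and oxidative stress genes, 9 were higher, 2 lower and 3 not past the test (adjusted p = 0.133), with HSP70 (AT3G12580) 8.28-fold higher and HSFA7A (AT3G51910) 3.92-fold lower. Of 15 abscisic acid and cold response genes, 7 were higher, 5 lower and 3 not past the test (adjusted p = 0.73), with LTI78 (AT5G52310) 14.7-fold higher and COR47 (AT1G20440) 2.6-fold lower. Tissue markers were read as a check on the make-up of whole seedlings. Among 7 root cell markers, 3 were higher, none was lower and 4 did not pass (adjusted p = 0.428), and PYK10 (AT3G09260), a root and hypocotyl beta-glucosidase, rose 4.41-fold from 1623 ± 473 to 7154 ± 584 CPM. Among 9 epidermis, guard cell and phloem markers, 1 was higher, 2 were lower and 6 did not pass (adjusted p = 0.993). One of the lower ones, ATML1 (AT4G21750), stood at 35.4 ± 2.68 CPM in Light and 51.9 ± 0.792 in Dark, and lost its call when libraries were scaled by their totals (log2 change -0.10, adjusted p = 0.432). Too few seed storage markers were tested to give a value.

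Across the 22 lists, 15 passed camera's preset correlation of 0.01, 10 higher and 5 lower in Light, and 0 passed with an estimated correlation, where 4 had an unadjusted p below 0.05. The lowest adjusted p there was 0.192, and the tetrapyrrole list failed at an estimated correlation of only 0.039. With that setting camera also rests on the few residual degrees of freedom of 6 libraries. Failing it therefore does not show that correlation alone explains a list's shift. Splits of the 6 libraries with Light and Dark on both sides gave 8 to 15 lists at the preset correlation. The count of lists therefore did not set the real split apart. Those splits had unequal numbers of Light libraries on their sides, so they kept part of the Light-Dark difference. This comparison thus cannot decide whether the list shifts go with light. By limma's fry test 19 passed, which says only that the members of a list move, on balance, one way, without comparison with other genes. Counts adjusted over the list alone were the same as those over all genes in 20 lists and differed in 2, with 20 tetrapyrrole genes higher and 22 clock genes lower. In the 3' end processing and auxin lists, the median, the mean and camera's direction differed in sign: the medians were 0.16 and -0.16 and the means -0.06 and 0.51 on the log2 scale. The auxin median turned to 0.28 when libraries were scaled by their totals, and no other list's median changed sign.

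**Figure D1:**
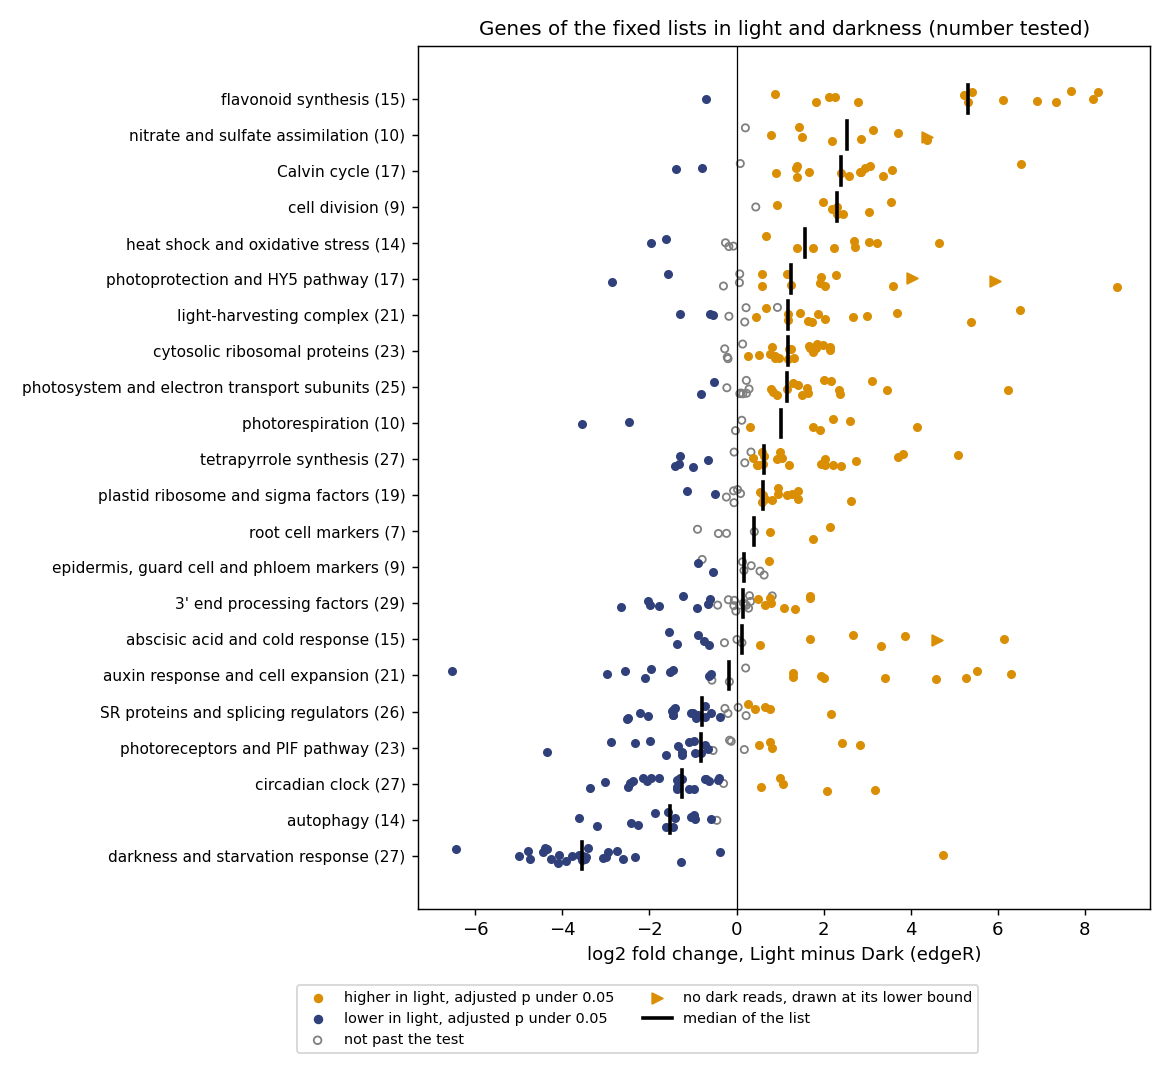
Log2 fold change, Light minus Dark, of each tested gene (points) in the 22 lists with enough tested genes, with the median of each list as a black bar. Genes of darkness and starvation lie to the left, with a median of -3.56, and those of flavonoid synthesis to the right, with a median of 5.31; triangles are genes with no Dark reads, drawn at their lower bound.

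APE2 (AT5G46110), the triose phosphate translocator of the chloroplast envelope, used its distal site on chromosome 5 at position 18700544 in 77.7% ± 4.77 of the reads of its 2 main terminal sites in Light, and in 14.7% ± 2.65 in Dark (SD, n = 3 each), against a proximal site at 18700435. PORB (AT4G27440), a protochlorophyllide reductase, moved in the same way between sites at 13727187 and 13727295 of chromosome 4, from 16.1% ± 1.02 distal in Dark to 77.9% ± 4.93 in Light. Its gene-level change fell just short of the threshold (log2 change 0.33, adjusted p = 0.0546 by edgeR's quasi-likelihood test). Over all genes with at least 2 sites, 2850 of 11074 (25.7%) had changed site usage by edgeR's differential exon usage test with Simes' method at an adjusted p of 0.05, over 29776 sites. Positions are those of the deposited table, on the TAIR10 build per the submitters' processing notes.

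Shifts between the 2 main terminal sites went mostly to the distal site in light. Among called pairs with a mean of at least 20 reads at each site and no overlap between the groups' libraries, the largest were found in AT5G27860, AT3G09455, APE2, PORB, AAP2 and AT5G20060. In AT5G27860 the distal site at 9874653 on chromosome 5, 321 nt beyond the proximal one at 9874974, held 68.4% ± 6.88 of the pair's reads in Light and 0.737% ± 0.339 in Dark. AT3G09455 went from 7.56% ± 4.03 distal in Dark to 67.7% ± 8.43 in Light, between sites at 2910469 and 2910357 of chromosome 3. AAP2 (AT5G09220), an amino acid permease, went from 14.7% ± 5.07 to 73.3% ± 16.1, between 2869026 and 2869096 of chromosome 5, while its level fell (log2 change -1.75). AT5G20060 had sites 51 nt apart, at 6779585 and 6779636 of chromosome 5, and its distal share was 2.22% ± 1.03 in Dark and 26.6% ± 5.14 in Light. On the log2 scale of distal over proximal reads these 6 genes changed by 3.98 to 8.08, and the largest adjusted p was 2.83e-06. The APE2 shift rested on where the terminal region was taken to end: counted from the annotated gene end, another pair of sites was compared and changed by 0.07 (adjusted p = 0.923).

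Under the same limits, the largest shifts to the proximal site in light were found in AT5G51410, TAF15b, AT3G58610, SQP1, AT2G14080 and AT1G32220. TAF15b (AT5G58470), an RNA-binding TAF15 protein, used its distal site at 23637694 on chromosome 5, 357 nt beyond the proximal one at 23638051, in 76.2% ± 0.415 of the pair's reads in Dark and 20.1% ± 0.972 in Light (adjusted p = 4.72e-11). AT2G14080 went from 77.7% ± 1.55 distal in Dark to 34.8% ± 13.6 in Light, between 5929471 and 5929860 of chromosome 2. AT3G58610 went from 93.5% ± 0.464 to 62.7% ± 7.91, with sites 33 nt apart at 21674764 and 21674797 of chromosome 3. In AT5G51410 the distal site at 20880827 on chromosome 5, 605 nt beyond that at 20881432, held 32.9% ± 9.36 in Dark and 0.426% ± 0.107 in Light. AT1G32220 went from 97.9% ± 3.61 to 84.0% ± 0.898 between 11609684 and 11609730 of chromosome 1, and only 2 of its 89 Dark reads lay at the proximal site, a pooled distal share of 97.8% with an exact 95% binomial interval of 92.1 to 99.7%. SQP1 (AT5G24150) had only 4 Dark reads, all at the distal site at 8172361 on chromosome 5, which allows a distal share of 39.8% or more, against 149 of 484 Light reads. Without Dark replicate 1, 2 or 3, AT5G51410 was compared at another pair of sites, whose log2 change was 1.4, 2.19 or 1.52, and SQP1 lost its call without Dark replicate 2 or 3 (log2 change -2.35 each, adjusted p = 0.118 and 0.14). TAF15b lost its call with a terminal region of 600 nt, where another pair gave 0.63 (adjusted p = 0.0699), and AT1G32220 when the outermost sites were compared (log2 change -2.42, adjusted p = 0.0885).

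**Figure D2:**
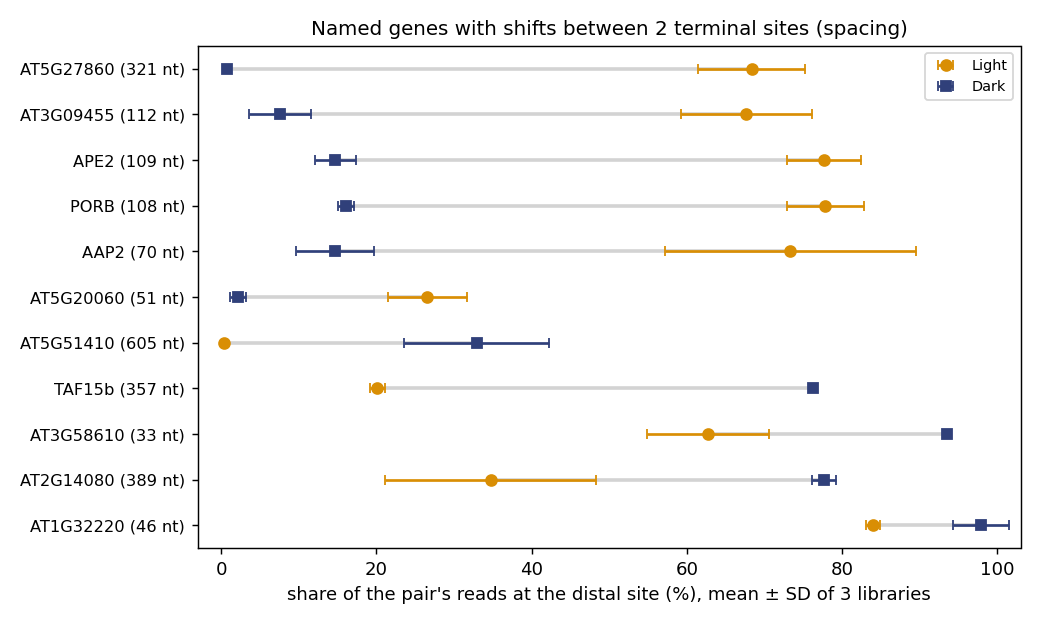
Share of reads at the distal of 2 terminal poly(A) sites, in percent, in Light (circles) and Dark (squares), as the mean and SD of 3 libraries; the spacing of the sites stands in brackets. AT5G27860, APE2 and PORB lie far to the right in Light, TAF15b and AT2G14080 in Dark; SQP1 is left out because it had 4 Dark reads.

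Of 10976 genes with a terminal pair, 2922 were called, 2280 toward the distal and 642 toward the proximal site in Light, and 1713 of them changed by at least 1 on the log2 scale. The distal share of calls was 78.0% (exact 95% binomial interval 76.5 to 79.5%, two-sided p = 1.88e-213), a p that describes these libraries, since genes are not independent replicates. Over all 10976 pairs, called or not, 63.9% changed toward the distal site, with a median log2 change of 0.25. The sites of a pair lay a median of 49 nt apart, with quartiles of 36 and 72 nt, so most shifts were short. Averaged over all pairs, 52.0% ± 0.445 of reads were at the distal site in Light and 48.9% ± 0.442 in Dark (SD, n = 3 each), a difference of 3.1 percentage points. An exact two-sided permutation test over the 20 arrangements gave p = 0.1, the smallest value that 3 against 3 libraries can give.

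**Figure D3:**
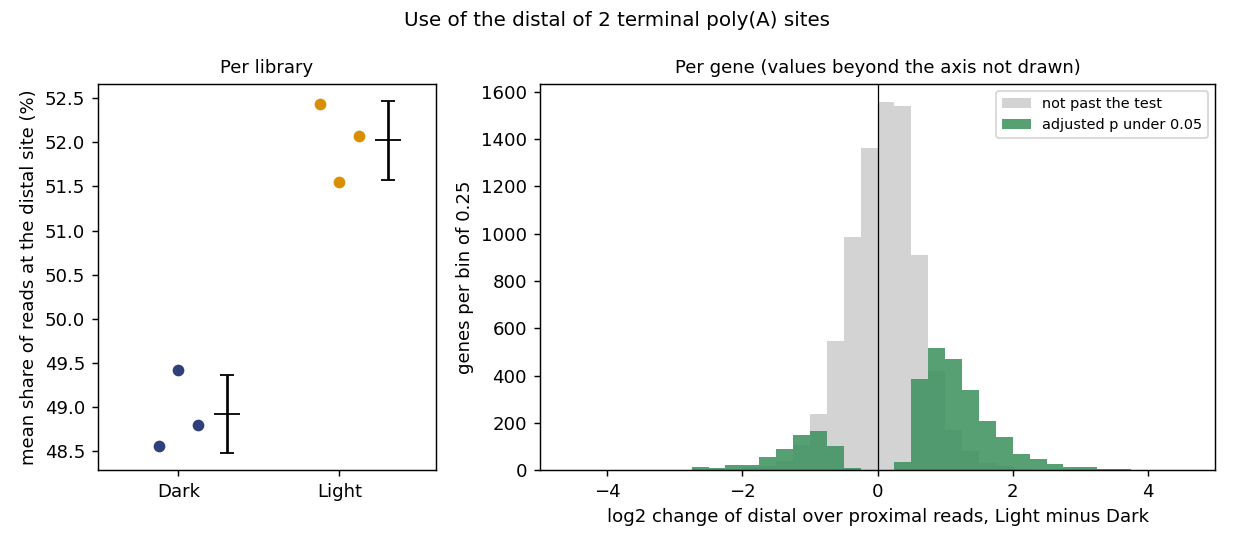
Left, mean percent of reads at the distal of 2 terminal sites in each library (points), with mean and SD; the Light libraries lie between 51.6 and 52.4% and the Dark libraries between 48.6 and 49.4%. Right, number of genes by log2 change of distal over proximal reads, overlaid for genes past the test (green) and not past it (grey); 2 genes lie beyond the axis.

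Of 20 photosystem and electron transport genes tested, 12 had changed site usage (odds ratio 4.34, adjusted p = 0.0245 by Fisher's exact test over 20 lists, chosen after seeing the data), with 5 called pairs toward the distal and 4 toward the proximal site. Abundant genes were called more often, from 5.73% in the lowest to 46.6% in the highest of 5 bins of mean expression. Within these bins the list did not pass (odds ratio 1.76, 95% interval 0.659 to 5.00, adjusted p = 0.853 by the exact conditional Mantel-Haenszel test), and neither did any of the other 19 lists in either test. The 3' end processing factors had 12 of 24 (adjusted p = 0.0992), the Calvin cycle 8 of 15 and the SR proteins and splicing regulators 11 of 24 (adjusted p = 0.168 each by Fisher's exact test). Within the bins the odds ratio of the 3' end processing factors stayed at 3.02 (95% interval 1.17 to 7.89, adjusted p = 0.291 by the Mantel-Haenszel test). That of the SR proteins and splicing regulators was 1.19 (0.474 to 2.92).

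Several factors of 3' end formation and splicing changed their own poly(A) sites. In CPSF30 (AT1G30460), a subunit of the cleavage and polyadenylation complex, reads upstream of the terminal region made up 48.9% ± 4.04 in Dark and 16.1% ± 2.41 in Light, and a single site at 10774386 on chromosome 1 went from 30.9% ± 4.15 to 7.58% ± 2.74 of the gene's reads. PCFS4 (AT4G04885) went from 28.5% ± 2.33 to 12.4% ± 1.29 upstream, mainly at 2475613 on chromosome 4. That site lay 416 nt before the reference site, just outside the terminal region, whereas the CPSF30 site lay 3120 nt before its own. The terminal pair of PCFS4 shifted to the proximal site in Light (adjusted p = 0.0139 by the terminal pair test). Its distal share was 22.6% ± 4.99 in Dark and 12.9% ± 1.6 in Light. The CPSF30 pair shifted to the distal site (adjusted p = 0.0173). Upstream reads of AT4G25550 went from 19.8% ± 1.65 to 7.88% ± 1.25. FPA (AT2G43410), an RNA-binding protein that acts on poly(A) site choice, went the other way, from 33.4% ± 2.76 upstream in Dark to 50.4% ± 3.01 in Light. Its site at 18030626 on chromosome 2 held 10.5% ± 0.66 of the gene's reads in Dark and 23.2% ± 1.75 in Light. The 4 adjusted p values of the upstream test lay between 1.19e-06 and 1.41e-04. In ESP1 (AT1G73840), a CstF-like factor, the distal of 2 terminal sites, at 27763635 on chromosome 1, held 37.3% ± 2.09 of the pair's reads in Light and 4.63% ± 1.08 in Dark (adjusted p = 2.43e-06).

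Among splicing regulators, RS40 shifted from 13.8% ± 1.47 distal in Dark to 27.9% ± 1.02 in Light, between 13027417 and 13027481 of chromosome 4, and SR34 from 89.2% ± 0.721 to 95.2% ± 0.684, between 629738 and 629810 of chromosome 1. ATU2AF35A (AT1G27650), a U2AF subunit, went from 47.9% ± 3.35 to 68.9% ± 4.54 distal. RSZ22 (AT4G31580) and SR30 (AT1G09140) passed only the test over all sites (adjusted p = 2.46e-08 and 5.68e-05). In RSZ22 the most distal site tested, at 15308943 on chromosome 4, held 11.2% ± 1.42 of reads in Dark and 4.11% ± 0.409 in Light. In SR30 the most distal site tested, at 2942571 on chromosome 1, went the opposite way, from 9.18% ± 1.77 in Dark to 20.0% ± 2.87 in Light. In all, 28 members of these lists passed at least 1 of the 3 site tests, and the 10 named here had the smallest adjusted p. Over all genes, 25.7%, 26.6% and 51.6% of those tested passed the site usage, terminal pair and upstream tests. Neither list passed for site usage after adjustment, so whether these lists differ from other genes stays open.

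Use of sites upstream of the terminal region, which yields shorter transcripts, changed in both directions. In PRIN2 (AT1G10522), a plastid redox-insensitive protein linked to chloroplast transcription, upstream reads fell from 68.5% ± 13.2 in Dark to 15.5% ± 3.45 in Light (SD, n = 3 each), mainly at 3469839 on chromosome 1, 1580 nt before the reference site. UGT85A1 (AT1G22400), a glucosyltransferase, went from 61.8% ± 7.4 to 19.2% ± 0.421, mainly at 7905678 on chromosome 1, AT2G37650 from 56.7% ± 5.09 to 17.5% ± 7.25 and AT1G79520 from 89.1% ± 4.66 to 52.2% ± 11.2. Shifts toward upstream sites in light were found in AT4G32440, from 1.85% ± 0.702 to 48.2% ± 2.93, mainly at 15658890 on chromosome 4, and in AT3G58980, from 6.07% ± 5.37 to 47.5% ± 12.6. GSTZ1 (AT2G02390), a zeta-class glutathione transferase, went from 0.727% ± 0.433 to 14.3% ± 3.19, mainly at 630796 on chromosome 2, and AT5G08060 from 0.699% ± 0.968 to 8.71% ± 2.72. The GSTZ1 site lay 426 nt before the reference site, just outside the 400 nt terminal region. The largest adjusted p of the 8 genes was 1.34e-05. With the terminal region counted from the annotated gene end, AT5G08060 changed in the opposite direction, with a log2 change of terminal over upstream reads of 1.12 (adjusted p = 9.96e-05) in place of -4.19.

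**Figure D4:**
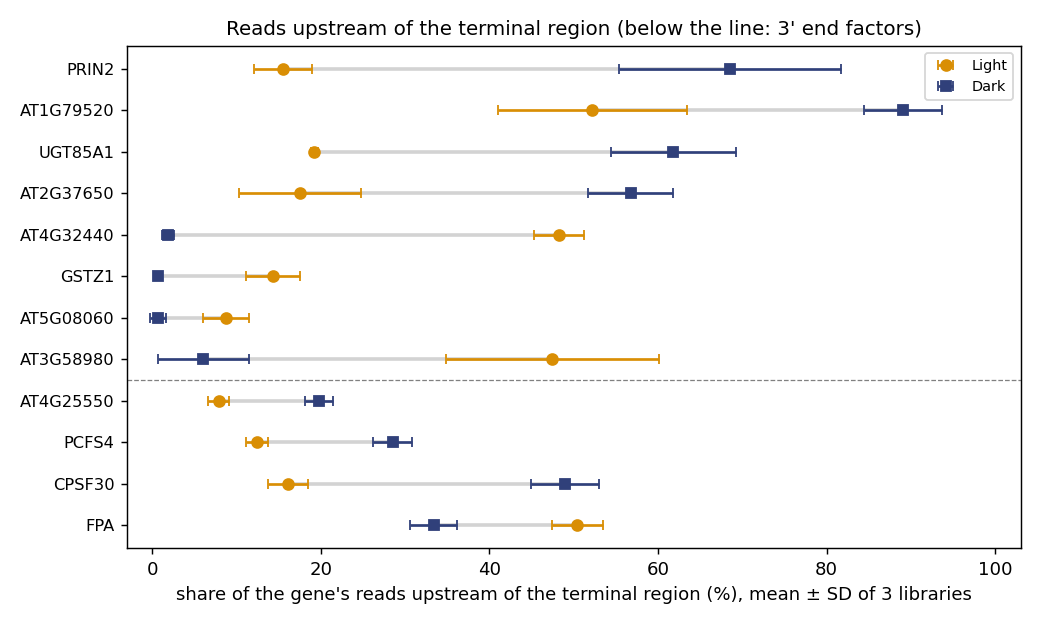
Percent of a gene's reads upstream of its terminal region in Light (circles) and Dark (squares), as the mean and SD of 3 libraries, for the named genes and, under the dashed line, for 4 factors of 3' end formation. PRIN2 and CPSF30 lie higher in Dark, AT4G32440 and FPA in Light.

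Of 490 genes with at least 5% of their reads upstream of the 400 nt terminal region and past the count filter, 253 (51.6%) were called, 170 with more and 83 with less upstream use in Light. That direction depended on where the terminal region was placed: counted from the annotated gene end, 479 of 916 genes were called, 213 with more and 266 with less upstream use. Upstream reads made up 0.398% ± 0.0221 of assigned reads in Light and 0.358% ± 0.021 in Dark, where the exact two-sided permutation test again gave its smallest value of p = 0.1.

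Genes called for expression were called for site usage slightly more often. Of genes called at the gene level, 26.7% had changed site usage, against 22.7% of the others, an odds ratio of 1.24 (95% interval 1.12 to 1.38, two-sided p = 4.62e-05 by Fisher's exact test over 11074 genes). Within 5 bins of mean expression the odds ratio over the 11074 genes was 0.921 (95% interval 0.822 to 1.03, two-sided p = 0.152 by the exact conditional Mantel-Haenszel test), so no excess was detected among genes of like expression. AT3G58610 and PORB were examples of changed site usage without a call at the gene level, and UGT85A1 and AAP2 of both together. PORB missed that call narrowly (log2 change 0.33, adjusted p = 0.0546 by edgeR's quasi-likelihood test).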

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

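These reads lay outside the comparisons of the report, and each class differed between Light and Dark in all 6 libraries. The minimum distance and read number of the antisense genes named elsewhere were chosen after seeing the data; the tests weighed here were set before their results were seen.

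Mitochondrial positions held 0.0955% ± 0.00706 of each Dark library and 0.0411% ± 0.00282 of each Light library (SD, n = 3 each), and plastid positions 0.00469% ± 0.000592 and 0.00363% ± 0.000384. Clusters at tRNA, snoRNA, snRNA or rRNA genes went the other way, with 0.0988% ± 0.0113 in Dark and 0.233% ± 0.0094 in Light. Clusters outside the protein-coding genes with a resolved strand, some of them in noncoding genes or pseudogenes, held 2.16% ± 0.191 in Dark and 1.38% ± 0.0366 in Light. Of these, the spans of AT3G06355 and AT3G06365, which lie beside rRNA genes in the reference, held 0.603% ± 0.133 and 0.122% ± 0.0179, and the remainder 1.56% ± 0.0589 and 1.26% ± 0.0192. Each exact permutation test of these 4 classes gave p = 0.1, the smallest that 3 against 3 libraries can give. Their explanations were not tested.

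Antisense reads held 0.222% ± 0.0128 in Dark and 0.185% ± 0.00315 in Light (exact permutation p = 0.1, the smallest possible). A few abundant clusters are argued against as the whole cause, since without the 20 largest clusters the Dark share was still higher by 0.0223 percentage points, with every Dark above every Light library. Spill from a gene's own sense reads is argued against as the whole cause by the median log2 change of antisense over sense reads. It was -0.50 over 389 genes (95% interval -0.76 to -0.28), which are not independent replicates. Spill from abundant neighbouring genes is not covered by this ratio. Antisense calls more than 1000 nt from a gene end included 160 whose sense reads were also called. Of these, 113 moved with the sense reads and 47 against. Most antisense calls, 172 of 203, were lower in Light, and the agreement to be had without any link was not computed. These counts therefore do not decide, and spill as a part of the cause stays open. Transcription in darkness may differ, and so may unannotated neighbouring genes; neither was tested.

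The excess of shifts to distal sites in light was weighed against 3 technical explanations. Small moves between adjacent cleavage positions are argued against as the whole cause by pairs at least 100 nt apart. Of their 524 calls, 83.0% went to the distal site (79.5 to 86.1%). All pairs tested lay a median of 49 nt apart, and for the closer pairs such moves stay open. A change in the genes' own level is argued against by genes not called at the gene level, with 77.4% of 641 calls (73.9 to 80.6%). A few abundant genes or low-count pairs are argued against by 5 bins of depth, of which the lowest had 73.2%. A difference between library batches stays open, since the labels give none. The excess may reflect light itself, as a hypothesis found and tested on the same data.

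The even split of genes higher and lower in Light depends on scaling: with library totals 68.3% of calls were higher. No value here decides which scaling is right, since total RNA per seedling was not analysed here, so the split and a change in total RNA cannot be told apart.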

How the results depend on the processing

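The region lengths of 250 and 600 nt, the annotated gene end, the 100 nt spacing, library totals, small RNA clusters kept, the set of genes not called and the list usage tests were chosen after seeing the data. Of 12232 genes, 7615 changed at least 2-fold. Of 2922 called terminal pairs, 1713 changed by at least 1 on the log2 scale. Of 1256 tested pairs at least 100 nt apart, 524 were called. Both counts are smaller by construction. Fisher's exact test on summed reads, which ignores replicate spread, gave 5553. Upstream calls went from 253 to 405 with no usage minimum and to 479 from the annotated gene end. Lists went from 15 to 0 with an estimated correlation (4 at an unadjusted p below 0.05) and were 19 by fry. The overlap odds ratio went from 1.24 to 0.921 within bins of expression. That of site usage calls in the photosystem list went from 4.34 to 1.76 within the same bins and no longer passed. The cause was not tested. Other tools, filters and scalings gave 11985 to 12665 genes, 2010 to 3944 genes with changed usage, 2462 to 3490 terminal pairs and 195 to 337 upstream genes, and the share to distal lay between 77.0 and 83.0%, or at 72.1% by Fisher's exact test on summed reads.

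Leaving out each replicate in turn gave 11483 to 12340 genes, 2030 to 2907 with changed usage, 2084 to 2842 terminal pairs, 77.2 to 80.7% to distal, 223 to 278 upstream genes, 15 lists, distal differences of 2.88 to 3.33 points and odds ratios of 1.18 to 1.31. AT5G51410 ranged from -6.72 to 2.19, as another pair of sites was selected without Dark replicate 1 (1.4), 2 (2.19) or 3 (1.52). Another pair also gave 0.63 for TAF15b at 600 nt, and AT5G08060 gave 1.12 from the annotated gene end. The labels share replicate numbers, but these did not pair the libraries: same-numbered deviations correlated at 0.051, 0.006 and 0.056. With the replicate block the counts were 12094, 2721, 2788 and 254, with 15 lists, 78.6% to distal and an odds ratio of 1.28. The alternative of intronic clusters only was not run, because introns are not marked in the gene table used. Site usage was called in 5.73% of genes in the lowest and 46.6% in the highest of 5 bins of expression.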

Other observations

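The added gene lists, the noncoding genes, pseudogenes and antisense genes and the genes named in this part were chosen after seeing the data. Aliphatic glucosinolate synthesis, which builds sulfur-rich defence compounds from methionine, rose in light in 20 of 21 genes tested, with 1 not past edgeR's test. IPMI1 (AT3G58990) stood at 81.5 ± 3.32 CPM in Light and 0.371 ± 0.179 in Dark (SD, n = 3 each), CYP83A1 (AT4G13770) at 82.1 ± 5.65 and 0.712 ± 0.163, and the regulator MYB28 (AT5G61420) at 27.4 ± 2.54 and 0.369 ± 0.244. Breakdown of branched-chain amino acids fell in 13 of 14 genes and rose in 1, AT5G09300. BCAT-2 (AT1G10070) stood at 33.7 ± 5.21 in Light and 741 ± 24.6 in Dark, IVD (AT3G45300) at 21.1 ± 2.73 and 406 ± 5.84, and ALDH6B2 (AT2G14170) at 124 ± 20.6 and 1386 ± 13.02. Of this list 7 members are also in the fixed lists. In strigolactone synthesis 2 of 5 genes were higher, 2 lower and 1 not past the test. These lists were picked because members had been seen to change, so no test of a list is given. CCD8 (AT4G32810) stood at 2.01 ± 1.71 in Light and 106 ± 37.3 in Dark, and D27 (AT1G03055), with no Dark reads, was at least 15.8-fold higher in Light.

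Of 377 spans of noncoding genes and pseudogenes tested by edgeR, 181 were lower and 57 higher in Light. GUT15 (AT2G18440) stood at 97.3 ± 13.6 CPM in Light and 433 ± 61.2 in Dark, AT2G14878 at 179 ± 16.7 and 1076 ± 59.2, and AT1G69252 at 43.1 ± 6.34 and 361 ± 49.5. AT3G06355, beside an rRNA gene, stood at 1047 ± 145 and 7158 ± 1361. Antisense reads more than 1000 nt from the end of any gene on their own strand were tested at 270 genes, of which 172 were lower and 31 higher in Light. Antisense reads at AT1G20910 were absent from Light and stood at 6.00 ± 1.08 CPM in Dark, at least 91.5-fold lower in Light, and those at MPK20 (AT2G42880) stood at 0.154 ± 0.0421 and 9.53 ± 4.06.

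Other splits of the 6 libraries into 3 and 3 were counted, 10 in all with the real one, which are too few for a share under 0.05. The real split gave 12232 genes, 2850 genes with changed usage, 2922 terminal pairs and 253 upstream genes, and the highest other gave 0 of each, so 1 split of 10 reached each real value. Every other split mixed Light and Dark on both sides, so the group difference added to the spread within each side. Low counts were therefore likely in advance and do not weigh against an accidental grouping. For lists the real split gave 15 and the other splits gave 8 to 15, so 2 of 10 splits reached it. The count of lists at the preset correlation therefore did not set the real split apart. It cannot decide on the list shifts either way, since the other splits, with unequal numbers of Light libraries on their sides, kept part of the Light-Dark difference.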
